A study of Mus musculus with 6 samples.

How the data were processed

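The samples were 6 RNA-seq libraries of mouse cells described as primary lung fibroblasts, 3 called NC and 3 called calumenin KD in the titles. Per the labels' protocols, total RNA was sequenced on an Illumina NovaSeq instrument as paired-end reads and aligned with HISAT2 2.0.5. The build was mm10, per the submitters' processing notes. The tool that counted reads per gene, its strand setting and the annotation release are not given in the sources used here. The authors deposited FPKM values for 54532 genes in the 6 libraries, with gene positions and biotypes beside them, and positions are given here as deposited. The gene length in bases was also deposited, per the file headers. Of 54409 gene identifiers shared with GENCODE mouse release M21, 98.33% had the same coordinates.

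FPKM times gene length gave whole multiples of a single step in each library for 100.0% of values within a tolerance of 0.01, so reads per gene and the depth of each library were recovered. Whether the authors counted reads or fragments is not stated, and the word reads is used throughout. The library size behind the deposited FPKM differed from the sum of recovered reads by a factor of 0.987 to 1.02. Median-of-ratios factors computed on the deposited columns were 1.0037 in all 6, so an equal scaling of that kind was already in the values. The depth was 15907164 to 18312888 reads per library. Intervals and detection limits, the latter from 3 reads, cover counting error only.

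Groups were taken from the titles. Calls came from limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a linear model of group, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05 over genes with a mean of at least 1 FPKM over the 6 libraries. Fold changes are on that scale unless given as FPKM ratios. Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, for the 38 of 44 lists with at least 5 tested members. Of 1139 list genes 1138 were found in the file, 6 of them under another symbol. The planned main test was not a count test because the deposited values are FPKM, and voom on the recovered reads was run as an alternative. The groups, tests, gene lists, named-gene rule and the alternatives listed next were fixed before the data were examined.

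Named genes were Calu, the 22 senescence and fibrosis genes, and the 12 largest rises and 12 largest falls among protein-coding genes past the threshold, with a standard symbol and with KD values all on one side of all NC values. Up to 4 members past the threshold with the largest absolute change were also taken from each list, or the 2 members with the highest mean where none passed, and examples in the text come from these. The values of 1 gene that the rule names are not reported here, and it is left out of the plot of single genes. Alternatives were other pseudocounts (0.1 and 5), no filter or a filter of 5 FPKM, median-of-ratios, equal-total and quantile scaling, no trend, robust moderation, a replicate block, array weights, voom on recovered reads, each library left out, protein-coding genes only, and camera with an estimated correlation, camera on ranks or fry for lists. Removal of a GC and length trend (splines with 5 degrees of freedom) and of chromosome medians was added after the data were seen. GC content was available for 99.86% of tested genes.

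The code was tested on simulated data drawn from the real means and depths for the KD against NC comparison, with 12329 genes. Limma recovered 57.6% of genes changed 1.5-fold, 89.4% of those changed 2-fold and 100% of those changed 4-fold, and called 0.1% of unchanged genes. Voom on the simulated reads recovered more, 78.8%, 97% and 100%, and called 0.06% of unchanged genes. For a true log2 change of 1 the median fitted change was 0.857 with limma and 0.977 with voom. Camera called the simulated shifted list and 0 of 40 unshifted lists. Genes were drawn independently with a single dispersion, so the simulation does not test camera on correlated genes or with an outlying library. In the real data the estimated correlation was 0.366 for the interferon list and 0.436 for collagen maturation enzymes. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.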

Results

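RNA was sequenced from mouse cells that the labels call primary lung fibroblasts, the matrix-producing connective tissue cells of the lung. The 6 libraries fell into 2 groups of 3, NC and calumenin knockdown (KD). Calumenin, encoded by Calu, is a calcium-binding protein of the endoplasmic reticulum and the secretory pathway that belongs to the CREC family. The titles call the groups NC and KD while the sample descriptions call the same libraries wild type and knockout, and the labels do not spell out NC. The stated question was how loss of calumenin affects senescence and fibrosis signalling in fibroblasts. Reads recovered from the FPKM values came to 16280183, 16105634 and 15907164 in NC1, NC2 and NC3, and to 18312888, 16191536 and 16587420 in KD1, KD2 and KD3. At these depths 3 reads correspond to between 0.164 and 0.189 CPM. Nothing in the labels says that replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

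Calu was lower in the KD libraries than in the NC libraries, as the labels state for these groups. Calu, on the plus strand of chromosome 6 at 29348069 to 29377110 (ENSMUSG00000029767, mm10), had 220 FPKM in NC1, 227 in NC2 and 225 in NC3. It had 14.6 FPKM in KD1, 12.6 in KD2 and 13.1 in KD3. The mean was 224 ± 3.43 FPKM in NC and 13.4 ± 1.07 FPKM in KD (SD, n = 3 each), so KD cells kept 6.0% of the NC level, a 16.7-fold fall. On the log2(FPKM + 1) scale the difference was -3.96 (SE 0.07, limma adjusted p = 1.28e-06), with 3265 reads over the 3 KD libraries.

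The genes fixed in advance for senescence and fibrosis moved in both directions. Of the 22, 14 were expressed highly enough to test, 5 were higher in KD and 3 were lower. Among matrix genes, the fibrillar collagen chain Col1a1 rose from 149 ± 2.94 to 284 ± 16.2 FPKM (SD, n = 3), the adhesive glycoprotein Fn1 rose from 173 ± 3.21 to 295 ± 13.0 FPKM, and the metalloproteinase inhibitor Timp1 rose from 30.6 to 46.0 FPKM. Col3a1, another fibrillar collagen chain, fell from 24.6 ± 0.93 to 10.9 ± 0.59 FPKM. Mki67, a marker of cycling cells, rose from 105 ± 1.79 to 141 ± 11.7 FPKM.

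Limma on the log2(FPKM + 1) scale gave a difference of 0.92 (SE 0.06, adjusted p = 0.000193) for Col1a1, 0.77 (SE 0.06, adjusted p = 0.000273) for Fn1 and -1.11 (SE 0.06, adjusted p = 0.000111) for Col3a1. Timp1 differed by 0.57 (adjusted p = 0.00121) and Mki67 by 0.42 (adjusted p = 0.00754). The chemokine Ccl2 fell from 257 to 170 FPKM, a log2 difference of -0.60 (adjusted p = 0.00343). Glb1, which encodes the lysosomal beta-galactosidase, rose from 18.4 to 23.7 FPKM, a log2 difference of 0.35 (adjusted p = 0.0129), a call that ended without NC1, without NC2 or without KD2 (adjusted p between 0.0582 and 0.0633). The cell-cycle inhibitor Cdkn1a had 10.1 FPKM in NC and 10.6 in KD (adjusted p = 0.459). Trp53, which encodes p53, had 41.3 and 43.4 FPKM (adjusted p = 0.577), Tgfb1 had 6.15 in both groups (adjusted p = 0.966), and none of these passed the limma threshold. Col1a2 (403 and 450 FPKM, adjusted p = 0.122), the lamin gene Lmnb1 (81.5 and 95.9 FPKM, adjusted p = 0.111) and the stress-induced cytokine gene Gdf15 (39.0 and 31.9 FPKM, adjusted p = 0.0639) did not pass with all 6 libraries. Without KD1 these 3 passed in the same directions, with limma adjusted p of 0.00732 for Col1a2, 0.00688 for Lmnb1 and 0.0192 for Gdf15, and Trp53 was just past the threshold (0.05 after rounding).

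The other 8 genes had a mean below 1 FPKM and were not tested. Cdkn2a and Cdkn2b, the neighbouring genes for the cell-cycle inhibitors p16, p19ARF and p15, had 0 reads in all 6 libraries. Acta2 (0.0353 FPKM in NC and 0.0659 in KD) and Tagln (0.189 and 0.0591 FPKM), which are contractile genes of myofibroblasts, were close to the limit of detection. Ctgf (2 reads in NC and 0 in KD) and Lox (5 and 12 reads) were also near 0. Il6 had 1.31 FPKM in NC and 0.680 in KD. Postn, a matricellular protein gene, had 1.10 ± 0.13 FPKM in NC and 0.0898 ± 0.03 in KD (SD, n = 3), and without the filter it passed limma (adjusted p = 0.00252).

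**Figure D1:**
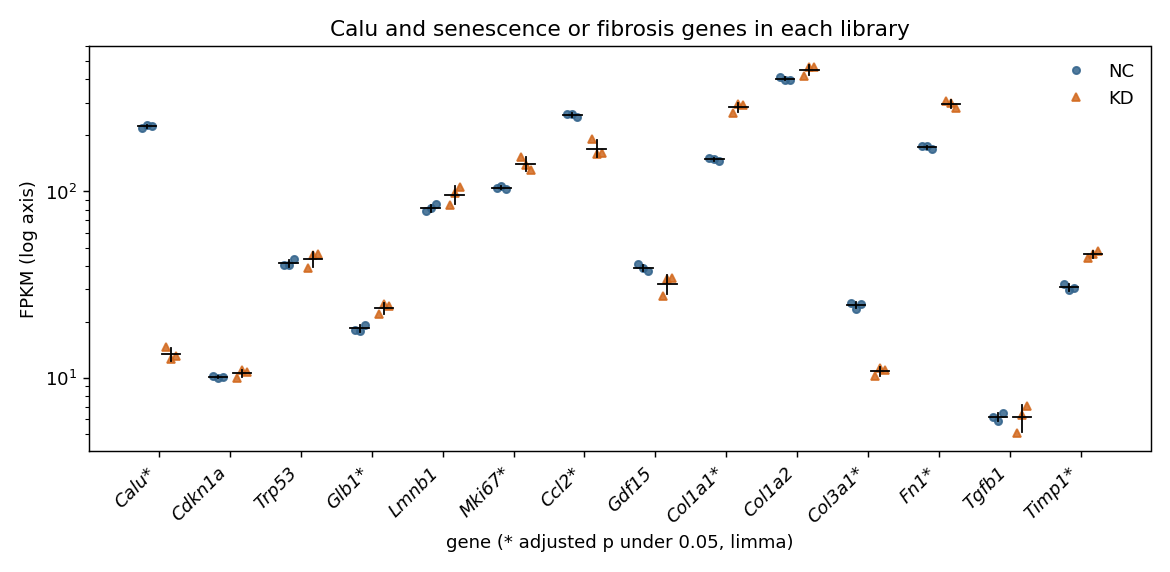
FPKM on a log axis of Calu and the tested senescence and fibrosis genes given in the text, in each library, with NC as circles and KD as triangles, and black lines at the mean and over ± 1 SD of 3 libraries. Calu lies between 220 and 227 FPKM in NC and between 12.6 and 14.6 in KD, and asterisks mark the genes with an adjusted p under 0.05 in limma.

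Across the transcriptome the largest falls included the fatty-acid transporter gene Cd36 and several genes induced by interferon, and 16 of the 40 largest were on the interferon-stimulated list. Cd36 fell from 341 ± 14.5 to 0.529 ± 0.25 FPKM (SD, n = 3), a 646-fold difference, and the chemokine gene Ccl5 fell from 37.5 to 0.389 FPKM. Rsad2 fell from 117 to 4.73 FPKM, Zbp1 from 31.1 to 1.53, Cxcl10 from 14.8 to 0.464, Ifit3 from 172 to 15.8 and Ifit1 from 97.0 to 9.09, all of them genes induced by interferon. Ptgs1, which encodes the prostaglandin synthase COX-1, fell from 11.7 to 0.118 FPKM. The largest rises were in Lce1g, Fmod and Ifi27. The small proteoglycan gene Fmod rose from 1.17 ± 0.21 to 18.4 ± 0.95 FPKM, and Rcn3, another CREC family member of the endoplasmic reticulum, rose from 8.25 ± 0.52 to 30.5 ± 3.35 FPKM.

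Limma tested 12299 genes, and 1344 were higher and 1672 lower in KD at an adjusted p under 0.05, or 24.5% of those tested. With an absolute log2 difference of at least 1 as well, 104 were higher and 213 lower. The log2(FPKM + 1) difference was -7.82 (SE 0.12) for Cd36 on chromosome 5 at 17781690 to 17888801, -4.81 (SE 0.14) for Ccl5, -4.42 (SE 0.23) for Rsad2 and -3.50 (SE 0.11) for Ptgs1. Zbp1 (-3.67), Ifit3b (-3.59), Cxcl10 (-3.43), Ifit3 (-3.37), Ifi44l (-3.33), Ifit1 (-3.31) and Gbp3 (-3.30) completed the 12 largest falls with Calu, and limma adjusted p was at most 8.11e-05 for each of the 12. Among the rises, the difference was 3.16 (SE 0.09, adjusted p = 7.13e-06) for Fmod on chromosome 1 at 134037254 to 134048277, 2.19 (adjusted p = 2.41e-05) for Ifi27 and 1.76 (SE 0.09, adjusted p = 8.11e-05) for Rcn3. Lce1g, a gene for a cornified envelope protein, went from 1 read over the 3 NC libraries to 714 over the 3 KD libraries (14.9 ± 1.07 FPKM in KD), and its neighbour Lce1f from 4 to 112 reads. Klhl30 (1.73), Ces1g (1.78), Syt8 (1.68), Clec11a (1.54), Islr (1.54), Gzme (1.54) and Wisp2 (1.54) completed the 12 largest rises by log2 difference. Ifit3 and Ifit3b, the Gbp genes and the Lce1 genes have near-identical relatives, so reads could be split between copies. These fold changes understate the change of low genes because of the pseudocount.

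Replicate spread was wider in KD than in NC. The chi-square statistic per degree of freedom between recovered read counts was 2.43 to 3.54 for NC pairs and 5.16 for KD2 against KD3, but 21.7 and 36.4 for KD1 against KD2 and KD3. KD1 also had the largest mitochondrial share of reads, 2.56% against 1.596% to 1.968% in the other libraries, and its deviation from the mean of the 6 libraries ran against GC content across genes (rho -0.41), where that of KD2 (0.34) and KD3 (0.49) ran with it, genes not being independent replicates. Without KD1, 2572 genes were higher and 2648 lower. Leaving out NC1, NC2, NC3 or KD2 gave 625, 590, 651 or 593 higher and 933, 923, 981 or 983 lower genes. Median differences also varied by chromosome, from -0.22 on chromosome 6 to 0.17 on chromosome 8. With each chromosome's median removed 1188 genes were higher and 1355 lower, and with a GC and length trend removed 2383 were higher and 2211 lower.

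Genes induced by type I interferon and genes for antigen presentation fell together. Of 37 tested interferon-stimulated genes 36 fell and 1, Ifi27, rose from 20.8 ± 0.41 to 99.0 ± 10.97 FPKM (SD, n = 3). The median log2 difference of that list was -1.80. Of 17 tested antigen presentation genes 13 fell, with a median of -0.62. The class Ib molecules H2-T23 and H2-T22 fell from 15.6 to 2.09 FPKM and from 49.3 to 13.4 FPKM, the proteasome activator gene Psme2 from 25.3 to 9.98 FPKM and the immunoproteasome gene Psmb9 from 10.7 to 4.09 FPKM.

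Adjusted over the list alone, 36 interferon-stimulated genes were lower and 1 higher, and 15 antigen presentation genes were lower and 1 higher. Without KD1, 36 interferon-stimulated genes and 15 antigen presentation genes were lower. Camera with a preset correlation of 0.01 gave an adjusted p = 2.25e-30 for the interferon list and 5.34e-08 for the antigen presentation list. With an estimated correlation neither passed (adjusted p = 0.385 with an estimated correlation for both). The estimates were 0.366 and 0.081. At that setting camera uses only the 4 residual degrees of freedom of the fit, for every list, so a loss there need not come from correlation. Other splits of the 6 libraries also put lists past camera, up to 12 of the 38, and the interferon list passed in all 9 of them. Those splits mix the groups unevenly and keep part of their difference, so these counts are not a rate of false calls. H2-T22 and H2-T23 belong to a family with near-identical members, so their reads could be split between copies.

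**Figure D2:**
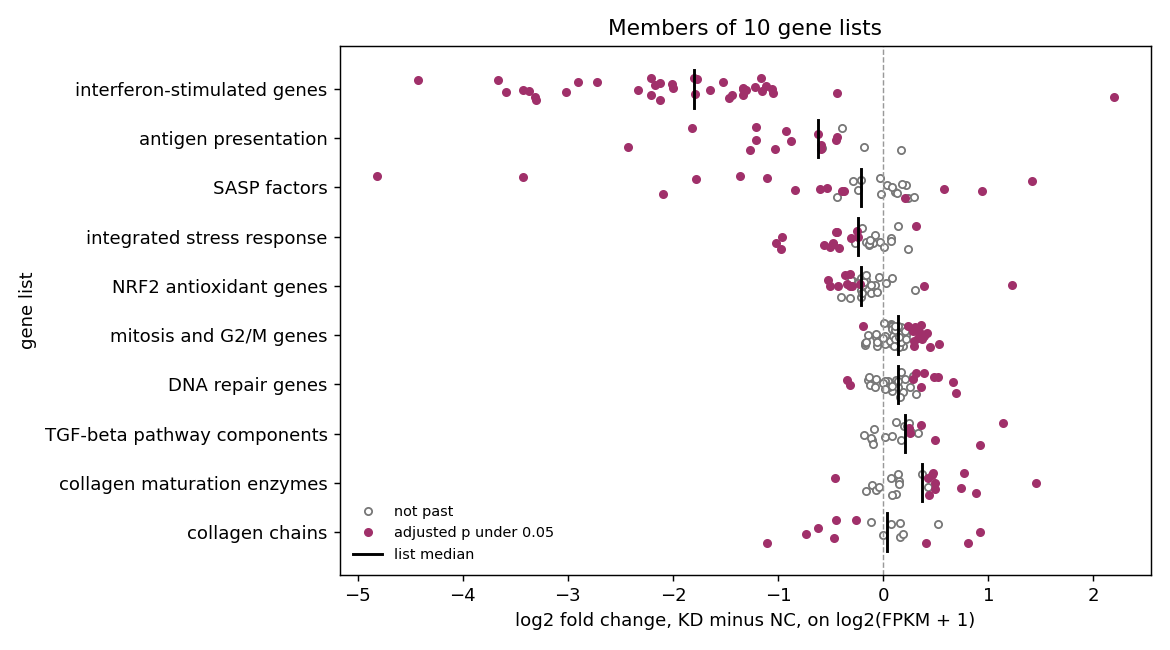
Log2 differences, KD minus NC on the log2(FPKM + 1) scale, for the tested members of 10 gene lists, with filled points for genes with an adjusted p under 0.05 in limma, open points for the rest and black lines for list medians. The interferon-stimulated genes lie left of 0 apart from Ifi27 at 2.19, and the list median is -1.80.

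Collagen-processing genes were more often higher than lower in KD, while collagen chains were divided. Of 23 tested collagen maturation enzymes 10 rose and 1 fell, and the median log2 difference was 0.37. The procollagen N-proteinase gene Adamts2 rose from 4.59 to 14.3 FPKM, the crosslinking enzyme gene Loxl1 from 75.9 to 141 FPKM, and the collagen-folding genes Fkbp14 and Fkbp10 from 2.46 to 4.88 and from 5.35 to 9.70 FPKM. Of 16 tested collagen chains 3 rose and 6 fell: Col4a5 rose from 7.10 to 13.2 FPKM beside Col1a1, and Col6a2 fell from 29.5 to 17.4 FPKM beside Col3a1. Of 18 tested matrix glycoproteins and proteoglycans 6 rose and 4 fell, with Bgn (39.0 to 96.8 FPKM) and Ogn (7.77 to 20.7 FPKM) higher and Vcan (4.996 to 1.01 FPKM) lower. Without KD1, 16 maturation enzymes rose and 2 fell, and 7 collagen chains rose and 6 fell. Without NC1, NC3 or KD2, 8 maturation enzymes rose and 0 fell. With chromosome medians removed, 13 maturation enzymes rose and 0 fell, and 5 collagen chains rose and 5 fell.

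Of 20 tested TGF-beta pathway components 6 rose and 0 fell. Ltbp4, which binds latent TGF-beta, rose from 29.3 to 65.9 FPKM, the latent TGF-beta docking receptor gene Lrrc32 from 6.13 to 12.5 FPKM, and the receptor gene Tgfbr2 from 13.2 to 19.1 FPKM. Of 18 tested TGF-beta response genes 3 rose and 6 fell, with Ltbp3 higher (53.6 to 86.7 FPKM) and Skil lower (8.14 to 5.19 FPKM). Among 8 BMP response genes 1 rose and 2 fell, and the BMP antagonist gene Grem1 fell from 2.47 to 0.102 FPKM. Of 14 YAP/TAZ-TEAD targets 7 rose and 2 fell, with Cyr61 higher (34.4 to 50.3 FPKM) and the tissue factor gene F3 lower (9.61 to 2.69 FPKM). Among 12 matrix proteases and inhibitors 4 rose, including Adamts5 and Timp2, and 4 fell, including the plasminogen activators Plau (6.94 to 2.09 FPKM) and Plat (1.86 to 0.593 FPKM). Of 17 tested contractile genes 5 rose, including Tpm2 (15.1 to 20.8 FPKM) and Actn1 (35.2 to 47.8 FPKM), and 2 fell. Without KD1, 11 TGF-beta components rose and 1 fell, 5 TGF-beta response genes rose and 7 fell, and 9 contractile genes rose and 2 fell. TGF-beta components numbered 4 higher and 0 lower without NC1, NC2, NC3 or KD2, and 7 and 0 without KD3. TGF-beta response genes numbered 2 higher and 4 lower without NC1, NC3 or KD2, 3 and 4 without NC2, and 2 and 5 without KD3. Contractile genes numbered 4 higher without NC1, NC2, KD2 or KD3, and 5 without NC3. Only 3 YAP/TAZ-TEAD targets rose without NC1, NC2 or KD2 and 4 without NC3, 0 BMP response genes rose without NC2, NC3 or KD3, and 1 contractile gene fell without NC1, NC2 or NC3 or with chromosome medians removed.

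By camera with the preset correlation the collagen maturation list (adjusted p = 0.000896) and the TGF-beta components (adjusted p = 0.00933) passed. With an estimated correlation they did not (adjusted p = 0.606 and 0.385 with an estimated correlation). The other 7 lists of this group had camera adjusted p of 0.209 to 0.959, and YAP/TAZ-TEAD targets passed with chromosome medians removed (0.0424). Adjusted over the list alone, 11 maturation enzymes rose and 1 fell, 6 TGF-beta components rose, 4 collagen chains rose and 6 fell, 7 matrix glycoproteins rose and 5 fell, 5 matrix proteases rose and 4 fell, 5 contractile genes rose and 2 fell, 3 TGF-beta response genes rose and 6 fell, 1 BMP response gene rose and 2 fell, and 8 YAP/TAZ-TEAD targets rose and 2 fell. The median and mean had different signs for collagen chains (0.03 and -0.03) and matrix glycoproteins (-0.03 and 0.21), and for matrix proteases both were negative (-0.13 and -0.03) while camera pointed up.

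Genes of mitosis and of DNA repair were higher more often than lower, and secreted factors of the senescence-associated list were lower more often than higher. Of 52 tested mitosis and G2/M genes 15 rose and 1 fell, by small amounts, with a median log2 difference of 0.14. Nusap1, a spindle protein gene, rose from 13.5 to 19.98 FPKM. Of 32 DNA repair genes 8 rose and 2 fell, with the glycosylase gene Neil3 rising from 7.004 to 12.02 FPKM and the mismatch repair gene Msh6 from 20.8 to 30.3 FPKM. Of 29 tested SASP factors 4 rose and 11 fell, and the epidermal growth factor family ligands Areg and Ereg fell from 5.92 to 0.618 FPKM and from 5.38 to 0.851 FPKM. Ccl5 and Cxcl10, given above, are also SASP list members and fell further by log2 difference. Cxcl10 is on the interferon-stimulated list as well, so the SASP and interferon lists are not separate evidence. Without KD1, 24 mitosis genes rose and 5 fell, 12 repair genes rose and 5 fell, and 7 SASP factors rose and 16 fell. Mitosis genes numbered 4 higher without NC1 or NC3, 5 without KD2, 6 without NC2 and 13 without KD3, with 0 lower in each, and 15 and 0 with chromosome medians removed. Repair genes numbered 5 higher and 0 lower without NC1, NC2 or KD2, 6 and 1 without NC3, 8 and 1 without KD3, and 6 and 1 with chromosome medians removed.

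Of 11 tested genes on the list of cell-cycle inhibitors and regulators 4 rose, including Cdkn2d (22 to 30.6 FPKM) and Glb1 as given above. The 1 that fell was Hmga2. Glb1, Hmga1 and Hmga2 are on that list but are not cell-cycle inhibitors. Of 29 p53 target genes 1 rose and 5 fell, among them Ddit4 (14.8 to 6.75 FPKM) and Tnfrsf10b (8.72 to 5.85 FPKM). Of 18 genes on the list of nuclear lamina genes and senescence-lost chromatin genes 3 rose, including Hmgb2 (30.0 to 42.5 FPKM) and H2afz (152 to 202 FPKM), and 0 fell. Of 41 DNA replication and G1/S genes 2 rose and 8 fell, a balance that depended on single libraries: without KD1, 11 rose and 12 fell, without NC1 1 rose and 0 fell, without NC2, NC3 or KD2 0 rose and 1 fell, without KD3 1 rose and 5 fell, and with chromosome medians removed 2 rose and 3 fell. Without KD1, 5 genes of the inhibitor list rose and 3 fell, 2 p53 targets rose and 9 fell, and 7 lamina and chromatin genes rose and 2 fell. Genes of the inhibitor list numbered 1 higher and 0 lower without NC2 or KD2, 2 and 0 without NC1, and 3 and 0 with chromosome medians removed. For p53 targets 0 rose and 2 fell without NC1, NC2, NC3 or KD2, and 1 rose and 3 fell without KD3 or with chromosome medians removed. Camera with the preset correlation gave adjusted p of 0.00163 for mitosis and 0.0171 for DNA repair. Both were lost with an estimated correlation (adjusted p = 0.55 for each with an estimated correlation), and DNA repair also without KD1 (camera adjusted p = 0.09). SASP factors did not pass (camera adjusted p = 0.062) but did so without NC1 (0.0401), NC2 (0.0463), NC3 (0.0476) or KD3 (0.0446), with no filter (0.0199), equal totals (0.0396), the GC and length trend removed (0.0394) or chromosome medians removed (0.0361). With an estimated correlation they did not (adjusted p = 0.503 with an estimated correlation). For the other 4 lists camera adjusted p was 0.217 to 0.959. Adjusted over the list alone, 15 mitosis genes rose and 1 fell, 9 repair genes rose and 2 fell, and 5 SASP factors rose and 13 fell. In the same way 4 genes of the inhibitor list rose and 2 fell, and 1 p53 target rose and 5 fell. For lamina and chromatin genes 3 rose, and 2 replication genes rose and 8 fell.

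In the endoplasmic reticulum group, integrated stress response genes were more often lower than higher, while Rcn3, a relative of calumenin, was higher. Of 29 tested integrated stress response genes 14 fell and 1 rose, with a median of -0.24. The transcription factor gene Ddit3, also called CHOP, fell from 48.3 ± 0.93 to 23.4 ± 2.80 FPKM (SD, n = 3) and Ppp1r15a, a phosphatase subunit gene induced by stress, from 10.5 to 4.94 FPKM. Of 22 tested CREC family and calcium-handling genes 6 rose and 2 fell. Rcn3 rose as given above, and Itpr2, a calcium release channel gene of the endoplasmic reticulum, fell from 4.44 to 1.53 FPKM. Among 33 chaperone and unfolded-protein genes 5 rose and 3 fell, with Pdia5 higher (11.1 to 17.4 FPKM) and the oxidoreductase gene Ero1l lower (128 to 52.0 FPKM). Without KD1, 5 stress response genes rose and 15 fell, 9 CREC and calcium genes rose and 4 fell, and 13 chaperone genes rose and 5 fell. Stress response genes numbered 0 higher and 10 lower without NC1, NC2 or KD2, and 0 and 14 without KD3. CREC and calcium genes numbered 2 higher without NC1, NC2, NC3 or KD2, with 1 lower except for 2 without NC1. Chaperone genes numbered 2 higher and 2 lower without NC1, NC3 or KD2, and 3 and 2 without NC2.

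Of 33 NRF2 antioxidant genes 9 fell and 2 rose. The thioredoxin reductase gene Txnrd1 fell from 56.7 to 39.0 FPKM and the cystine transporter gene Slc7a11 from 4.63 to 2.95 FPKM, while Sod3, which encodes an extracellular superoxide dismutase, rose from 22.9 to 54.9 FPKM. The vitamin K list had 5 tested members, of which 1 rose (Ggcx, the gamma-glutamyl carboxylase gene, 8.04 to 11.4 FPKM) and 1 fell. Camera with the preset correlation passed the integrated stress response (adjusted p = 0.000605) and the NRF2 list (adjusted p = 0.00253), and with an estimated correlation neither passed (adjusted p = 0.55 and 0.385 with an estimated correlation). CREC and calcium handling (camera adjusted p = 0.163, or 0.00667 with a filter of 5 FPKM), chaperones (0.276) and vitamin K (0.608) did not pass. Adjusted over the list alone, 14 stress response genes fell and 1 rose, 10 NRF2 genes fell and 2 rose, 10 CREC and calcium genes rose and 3 fell, 7 chaperone genes rose and 3 fell, and 1 vitamin K gene rose and 1 fell. Without KD1, 16 NRF2 genes fell and 3 rose, and 2 vitamin K genes rose and 1 fell. NRF2 genes numbered 3 lower without NC1, 4 without NC2 or NC3, 5 without KD2 and 10 without KD3, with 1 higher in each. Without NC1, NC3 or KD3, 1 vitamin K gene rose and 0 fell.

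Genes of lipid handling and glycolysis included several clear falls, although their lists did not pass. Of 26 tested fatty-acid and adipogenic genes 5 rose and 10 fell, and Plin2, a lipid droplet coat gene, fell from 110 ± 3.24 to 56.9 ± 0.56 FPKM (SD, n = 3), Pparg from 41.2 to 25.01 FPKM and Fabp4 from 9.69 to 5.08 FPKM. Of 30 glycolysis and hypoxia genes 3 rose and 8 fell, with Hk2 lower (17.0 to 9.61 FPKM) and the carbonic anhydrase gene Car9 higher (17.1 to 38.7 FPKM). Of 53 nuclear genes for oxidative phosphorylation 2 rose and 10 fell, among them Ndufa9 (36.9 to 27.0 FPKM), and of 12 mitochondrially encoded genes 0 passed, with mt-Co1 at 5829 and 5527 FPKM. Of 20 sterol synthesis genes 1 rose (Dhcr7, 7.50 to 11.5 FPKM) and 6 fell. Of 37 lysosome and autophagy genes 9 rose, including Naglu (8.49 to 15.2 FPKM), and 10 fell, including Lipa (58.1 to 37.1 FPKM). Without KD1, 9 fatty-acid genes rose and 11 fell, 7 glycolysis genes rose and 9 fell, 11 oxidative phosphorylation genes rose and 12 fell, 2 mitochondrially encoded genes fell, 5 sterol genes rose and 8 fell, and 15 lysosome genes rose and 11 fell. Fatty-acid genes numbered 2 higher and 7 lower without NC1, NC2, NC3 or KD2, and 2 and 8 without KD3, and glycolysis genes 1 and 7 without NC2 or KD2. Oxidative phosphorylation genes numbered 0 higher and 3 lower without NC1, NC2 or KD2, 1 and 3 without NC3, and 0 and 12 without KD3. Sterol genes numbered 1 higher and 1 lower without NC1, NC2 or NC3, and 1 and 2 without KD2, and 1 mitochondrially encoded gene rose without KD3. Lysosome genes numbered 6 higher and 3 lower without NC1, 7 and 4 without NC2, 7 and 5 without NC3, and 6 and 5 without KD2. With chromosome medians removed, 3 fatty-acid genes rose and 11 fell, 1 oxidative phosphorylation gene rose and 5 fell, 1 sterol gene rose and 3 fell, and 6 lysosome genes rose and 3 fell.

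Of 56 ribosomal protein genes 3 rose and 3 fell, counts that depended on single libraries. Ribosomal genes numbered 16 higher and 5 lower without KD1, 0 and 8 without KD3, 0 and 1 without NC1, 0 and 2 without NC2 or NC3 or with chromosome medians removed, and 1 and 2 without KD2. Of 19 heat-shock genes 2 rose and 5 fell, with the mitochondrial chaperonin genes Hspd1 (376 to 239 FPKM) and Hspe1 (102 to 62.6 FPKM) lower. Among 21 NF-kB response genes 3 rose and 5 fell, with Ccl7 lower (159 to 73.1 FPKM) and Nfkbie higher (4.39 to 7.60 FPKM), and the list had a positive median (0.05), a negative mean (-0.04) and a camera direction of down. Of 8 complement genes 2 rose, including C1s1 (4.13 to 8.86 FPKM), and of 24 immediate early genes 2 rose and 6 fell, including Dusp5 (6.15 to 2.44 FPKM) and Myc (75.1 to 51.0 FPKM). Camera adjusted p for these lists and for the lipid, glycolysis, respiratory, sterol and lysosome lists lay between 0.253 and 0.885. Oxidative phosphorylation passed, as lower, without KD3 (0.011), and ribosomal genes passed, as higher, with array weights (0.0291). Adjusted over the list alone, 5 fatty-acid genes rose and 11 fell, 3 glycolysis genes rose and 8 fell, 1 oxidative phosphorylation gene rose and 9 fell, 0 mitochondrially encoded genes passed, 2 sterol genes rose and 8 fell, 10 lysosome genes rose and 11 fell, 0 ribosomal genes rose and 2 fell, 3 heat-shock genes rose and 5 fell, 4 NF-kB genes rose and 5 fell, 2 complement genes rose, and 4 immediate early genes rose and 6 fell. Without KD1, 3 heat-shock genes rose and 8 fell, 7 NF-kB genes rose and 6 fell, and 6 immediate early genes rose and 6 fell. Heat-shock genes numbered 0 higher and 4 lower without NC2, NC3, KD2 or KD3, 1 and 4 without NC1, and 1 and 6 with chromosome medians removed. NF-kB genes numbered 1 higher and 4 lower without NC2 or KD2. Complement genes numbered 1 higher and 0 lower without NC1, NC2, NC3 or KD2, and 1 and 1 without KD3. For immediate early genes 0 rose without NC1, NC2, NC3, KD2 or KD3, and 4, 4, 3, 5 and 5 fell.

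Fibroblast subtype markers were sparse in both groups. Of 17 alveolar fibroblast markers 5 were tested, of which 2 rose, Pdgfra (7.05 to 11.2 FPKM) and Macf1 (14.0 to 17.8 FPKM), and 2 fell, Plin2 and Mettl7a1 (8.23 to 4.51 FPKM). Of 23 adventitial markers 7 were tested and 0 passed, with Serpinf1 at 232 and 221 FPKM. Of 16 pathological fibroblast markers 6 were tested and 1, Grem1, fell, and that list had a positive median (0.06) with a negative mean (-0.22) and a camera direction of down. Camera adjusted p of these lists was 0.794 to 0.885, and adjusted over the list alone the counts were the same as over all genes. Without KD1, 1 adventitial marker rose and 2 fell, and 0 pathological markers rose and 2 fell. With chromosome medians removed 1 pathological marker rose and 1 fell.

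Markers of other cell types were mostly below the 1 FPKM filter. Of 26 macrophage and leukocyte markers 5 were tested and 2 fell, Mpeg1 (2.36 to 0.619 FPKM) and Cd74 (75.0 to 61.7 FPKM), and Cd74 lost its call without NC1, NC2 or KD2 (limma adjusted p 0.0807 to 0.104), while 4 markers fell without KD1. The camera adjusted p of that list was 0.0829, or 0.0476 without NC3, and 3 fell adjusted over the list alone. Of 24 lung epithelial markers 1 was tested and 0 passed, with Hopx at 3.52 and 3.88 FPKM. Of 22 endothelial markers 2 were tested and 1 rose, Plvap (6.24 to 10.3 FPKM), a call that ended without NC2, NC3 or KD2 (limma adjusted p 0.0536 to 0.0723). Of 15 mesothelial markers 3 were tested and 0 passed (Msln 14.2 and 12.4 FPKM, Cldn15 52.9 and 63.7 FPKM), with 1 up and 1 down adjusted over the list alone, 1 up without KD1, 1 down without KD3 and 2 down with chromosome medians removed. Of 18 pericyte and smooth muscle markers 4 were tested and 1 fell, Pdgfrb (36.9 to 30.3 FPKM), a call that ended without NC1, NC2, NC3 or KD2 (limma adjusted p 0.0886 to 0.111). Adjusted over the list alone, 1 endothelial marker rose and 1 pericyte marker fell. No red blood cell or platelet marker and no X-inactivation or Y-linked gene reached the filter, and the highest group mean was 0.504 FPKM for Gp9 and 0.0186 FPKM for Xist.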

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

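The alternatives were planned except removal of a GC and length trend and of chromosome medians, which were chosen after the results were seen. Of the 3016 calls, 6 changed sign with chromosome medians removed, and 0 were called in the other direction at any setting. Many calls were not kept, however. With chromosome medians removed 69.8% of them stayed past the threshold. The share kept was 50.8% without NC1, 49.3% without NC2, 52.8% without NC3 and 51.6% without KD2. It was 98.2% without KD1 and 74.5% without KD3. Calu kept its direction and call throughout (log2 difference -4.06 to -3.64). Leaving out each library in turn gave 590 to 2572 higher genes and 923 to 2648 lower genes. The highest counts came without KD1 (2572 and 2648), and the counts were 625 and 933 without NC1, 590 and 923 without NC2, 651 and 981 without NC3, and 593 and 983 without KD2. Those fits had fewer samples, but what made KD1 differ was not tested. Requiring a log2 difference of at least 1 left 104 higher and 213 lower genes by construction, and removing the GC and length trend raised the higher genes to 2383, the cause of which was not tested. Median-of-ratios scaling kept all 3016 calls because its factors were equal. A fit with the replicate number as a block called 1050 higher and 1383 lower genes and changed no list call. Deviations from the group mean correlated at 0.079, -0.043 and 0.154 for same-numbered samples, and at -0.158 to 0.082 for differently numbered ones. With 3 samples per group these values are tied together, so they do not settle whether the numbers pair the samples. With an estimated correlation 0 lists passed camera, against 8 with the preset one. Fry passed 25, but it asks whether members change at all, and camera whether they change more than other genes. The adjusted p with an estimated correlation was 0.606 for collagen maturation enzymes, 0.55 for mitosis, DNA repair and the integrated stress response, and 0.385 for TGF-beta components, interferon-stimulated genes, antigen presentation and NRF2 genes. TGF-beta components had an estimated correlation of 0.011, near the preset 0.01, yet their unadjusted camera p rose from 0.00172 to 0.0362. Correlation alone thus does not account for the losses at that setting, which uses 4 residual degrees of freedom. DNA repair also fell short with array weights (0.076) and without KD1 (0.09), with adjusted p of 0.00371 to 0.09 over fits that left out a library; the cause was not tested. Lists that did not pass camera but did so at another camera setting were SASP factors (lowest adjusted p 0.0199, no filter), CREC and calcium genes (0.00667, filter of 5 FPKM), YAP/TAZ-TEAD targets (0.0424, chromosome medians removed), ribosomal genes (0.0291, array weights), oxidative phosphorylation (0.011, without KD3) and leukocyte markers (0.0476, without NC3). Of 148 named genes past the threshold, 115 passed in each of the 6 fits that left out a library and 33 lost their call in at least 1. Over all settings 2996 single-gene results stayed on their side of the threshold, 180 dropped below it and 22 rose past it. Acta2 and Ctgf had 9 and 2 reads over the 6 libraries; the depth was enough to place both near 0, and both lay below the filter.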

Other observations

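Of the tests of explanations given here, those of depth and of copy number were written down before their result was seen, and the others were chosen only after the result was seen. The interferon-stimulated and antigen presentation lists together held 49 lower genes, and the 40 largest falls by log2 difference held 16 of the interferon list. Transcripts of type I interferons themselves were low. Ifnb1 had 18 reads over the 3 NC libraries and 2 over the 3 KD libraries, and Ifna4 had the same 18 and 2. Both were below the filter, and Ifng had 0 reads in all 6 libraries. The receptor genes Ifnar1 (10.6 and 11.4 FPKM) and Ifnar2 (6.75 and 7.87 FPKM) did not pass the limma threshold (adjusted p = 0.22 and 0.248).

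The fall of the interferon-stimulated genes was weighed against a scaling effect, leukocytes and a higher interferon level in NC. Rescaling to equal totals or quantile normalization left the list median at or below -1.775, while the median of all genes stayed within 0.0338 of 0. The FPKM sums were already close, from 277587 in KD2 to 289537 in NC3, so rescaling could not have moved the list near 0. The rescaling test could thus not have come out otherwise, and what the sums show is that the columns differ too little in total to give the fall. Over 9 abundant leukocyte transcripts the median NC level was 0.0172 FPKM, which argues against leukocytes; an earlier bound, all 9 below 1 FPKM, was not met because Cd74 (75.0 FPKM) and Lyz2 (1.48 FPKM) exceeded it, and the median was chosen in its place after those levels were seen, with 7 of the 9 under 0.1 FPKM. Ifnb1 was 9.37 times higher in NC than in KD (95% counting interval 2.34 to 87.0), with both KD reads from KD2: the ratio was 6.24 without KD1 (1.51 to 56) or KD3 (1.58 to 58.7), and without KD2 Ifnb1 was at least 2.22-fold higher in NC, against 3 reads per library. A candidate explanation is thus more interferon production in NC, although Ifnb1 can itself be raised by interferon signalling and the order of events stays open. The design does not separate loss of Calu from delivery of the knockdown or from another difference between the cultures.

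Median differences shifted by chromosome, alike in the 3 KD libraries: after the GC and length trend was removed, chromosome 10 lay at -0.20, -0.18 and -0.18 in KD1, KD2 and KD3, and chromosome 8 at 0.17, 0.18 and 0.17. The SD over the 20 chromosomes was 0.106 after that removal against 0.111 before, which argues against GC content or gene length as the whole cause, and 1000 shuffles of genes gave at most 0.022, so random placement of changed genes does not account for it. A copy number difference between the cultures is a candidate explanation: the 4478 genes at 0.2 to 1 FPKM on the 20 chromosomes, not among those tested, shifted with the tested genes of their chromosome (Pearson r = 0.84, Spearman rho 0.877, permutation p = 1e-05 for each with 100000 resamples, the smallest they can give, and 1e-05 after Benjamini-Hochberg over these 2; r = 0.749 without the 2 chromosomes farthest from the median). That test replaced an earlier one, the 77.6% of chromosome 10 genes that were lower, which was set aside because chromosome 10 had been picked for its median. A shared shift of low and tested genes does not single out copy number. In windows of 50 genes some shifts were uneven. Chromosome 1 windows lay at -0.463 to -0.133 up to position 97606318 and at -0.074 to 0.062 beyond. A chromosome 6 window at 48523518 to 54595111 lay at 0.031. Chromosome 8 windows all lay at 0.118 to 0.236. Of the 10 splits of the 6 libraries only the real one, 1 of 10, gave so large an SD (0.1061, the highest other 0.0394), and 10 splits are too few for a share under 0.05. Every other split mixes the groups and so dilutes a difference between them, which makes a smaller SD there unavoidable.

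Several genes that fibroblasts usually express had next to no reads: Dcn had 3 reads over all 6 libraries, Lum, Eln and Tcf21 had 0, and Cdkn2a and Cdkn2b had 0 although their neighbours Mtap (2.59 and 2.90 FPKM) and Klhl9 (16.4 and 23.6 FPKM) on one side were expressed, while Dmrta1 on the other was near 0 (0.0699 and 0.0215 FPKM). They were brought together only after their values were seen, although Cdkn2a and Cdkn2b were among the 22 genes fixed in advance. Too little depth is argued against, because 3 reads were worth at most 0.161 FPKM for the 11 such genes. Xist and 4 Y-linked genes reached at most 0.0392 FPKM in any library, which argues against an unaltered XX or XY culture, and Col1a2 (403 and 450 FPKM) and Vim (602 and 559 FPKM) remained high. The Hox genes Hoxa9 (13.3 FPKM in NC and 14.1 in KD), Hoxa10 (25.6 and 29.2), Hoxc9 (9.82 and 8.87) and Hoxc10 (36.2 and 29.9) were also expressed. Their levels were not compared with those of lung fibroblasts, so the tissue of origin was not tested. A hypothesis is that the cells may have been a long-passaged or altered line rather than a fresh primary culture. No genotype was analysed here.

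The 3016 changed genes were given by the real split alone, 1 of 10 splits. The highest count of the others was 0 by limma, with up to 1013 genes at an unadjusted p under 0.05. For gene lists, 4 of the 10 splits put at least 8 lists past camera, the real one included, and the highest other split gave 12. Every other split still mixes the groups unevenly and so keeps part of their difference. Differences between libraries of the same group enter these splits as well, so the part kept need not account for all of their passes. The interferon list passed in all 9 of them, and antigen presentation, mitosis, the integrated stress response and NRF2 in 6. Collagen maturation, DNA repair and TGF-beta components passed in 3. For 4 lists the smallest camera adjusted p of another split lay below that of the real one: 0.000682 against 0.00163 for mitosis, 8.27e-05 against 0.000605 for the integrated stress response, 0.00299 against 0.0171 for DNA repair and 0.00599 against 0.00933 for TGF-beta components. No share under 0.05 can come from 10 splits, so neither count says whether chance is excluded.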
